A study of Mus musculus with 8 samples.

How the data were processed

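Colon lamina propria cells of mice were profiled with 10x Genomics 3' HT single-cell RNA sequencing with hashtag antibodies. Per the labels' protocols, the cells came from 4 tamoxifen-treated mice carrying floxed Rgs14 and a Cx3cr1-driven recombinase (group Rgs14 KO) and from 4 wild-type littermates (group Control). The epithelium was stripped with EDTA, the rest digested with collagenase, and CD11b+ cells that were also CCR2+ or CD64+ were sorted. Mice of 1 genotype shared a well, so wells 1 and 2 hold Rgs14 KO cells and wells 3 and 4 hold Control cells. The series title names experimental colitis; the labels of the libraries give no colitis treatment or day. The series title also names Rgs14 as a risk gene of inflammatory bowel disease (IBD).

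Each well gave 1 gene expression matrix and 1 hashtag matrix over unfiltered barcodes. The deposited gene expression values are estimated counts (expected counts) of unique molecular identifiers (UMIs): between 96.8% and 96.9% of the entries were whole numbers, and sums per gene were rounded to whole numbers before each test. The deposited hashtag values are counts of UMIs per tag. Per the submitters' processing notes, the authors used STARsolo, STAR 2.7.10a and the mm10 genome build; other settings are not given in the sources used here. The plan fixed beforehand had assumed whole counts. The matrices list 22544 features, of which 22428 matched a gene of the mm10 annotation; Cre and ERT2 sequences are among the 116 without a match. Hashtag barcodes were joined to gene expression barcodes by complementing bases 8 and 9. On the barcodes with the most gene expression UMIs, the median of hashtag UMIs was 0 in each well without this step. With it the median lay between 1258.5 and 1619.5.

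Barcodes were taken as cells when their UMIs reached a 1 in 10 share of the 99th percentile of the top 20000 barcodes of their well (thresholds of 3032, 3781, 3230 and 3149 UMIs in wells 1 to 4), with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. A tag was called present from a 2-component Gaussian mixture on log(count + 1), with a separation of at least 2, and cells with exactly 1 tag were kept. Hashtag 1 was not detected in well 2 (median 43.0 UMIs per cell, separation 0.230). Hashtag 2 had a median of 1434 UMIs per cell there and a separation of 1.01, also under the limit of 2. Cells of well 2 were kept if hashtag 2 exceeded 4 times the median of hashtag 1. Doublets with both tags were removed (485, 1302 and 1190 in wells 1, 3 and 4). Of the rest, the cells with the highest Scrublet scores were removed, as many as the cross-tag doublets imply for doublets within a tag (514, 1521, 1353 and 1251 in wells 1 to 4); well 2, where no cross-tag doublet can be seen, used the mean total doublet rate of the other wells and lost 23.0% of its cells.

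The replicate was the hashtag within a well. Replicates are named by well and tag: 1-1, 1-2 and 2-2 for Rgs14 KO, and 3-1, 3-2, 4-1 and 4-2 for Control. The sole replicate of well 2 may hold 1 mouse or both. The plan had 8 mice; the hashtags gave 7 replicates, 3 against 4, which have 35 arrangements and a smallest two-sided exact p of 0.0571. The plan also named the wells as replicates should hashtags fail, without foreseeing that only 1 well would; the 7 replicates were kept on the hashtag counts alone, before any gene was tested, and counts from well sums stand beside the counts of genes.

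Cells were clustered with scanpy 1.11.5 (Python 3.11.15) on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, without immunoglobulin, mitochondrial and sex-linked genes, Rgs14, Cx3cr1, Cre and ERT2. A cluster was called "X-like" when at least 3 markers, and at least 50.0% of the class's measured markers, were raised at least 2-fold over the other cells and seen in at least 10% of its cells, and no other class had more markers among its top 10 genes. The markers were fixed before the data were examined, as were the tests, the alternatives, the gene lists and the rule for naming genes; the share of markers that a name needs was set afterwards. Of 25 clusters, 19 carried a name from 10 classes; the 6 unnamed clusters held 13.0% of the cells.

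Counts were summed per replicate and class and tested with edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg at 0.05). The difference of the genotype effect between macrophage-like and monocyte-like cells was tested as an interaction with the replicate as a block. Of 30 gene lists, those with at least 5 tested members went through camera (limma 3.58.1) with its preset correlation of 0.01 on log2 CPM with a prior count of 2. Camera with an estimated correlation and fry were the alternatives. Shares of cells were compared by exact two-sided permutation tests of the difference of means. Other alternatives were DESeq2 1.42.0, relative log expression scaling, no low-count filter, sums per well, limma-voom with the well as a random block, each cell thinned to 3000 UMIs with equal cell numbers, each replicate left out, at least 1000 UMIs and 500 genes in place of the thresholds per well, mitochondrial limits of 5% and 20%, no Scrublet step, hashtags assigned by a 4-fold ratio, and Leiden resolution 0.5. Chosen after seeing the data were hashtags assigned by 3 Gaussians in the plane of both tags, the largest macrophage-like cluster alone, monocyte-like cells with unnamed cluster 1, Rgs14 by macrophage-like cluster (with and without the low-count filter, and as an interaction of clusters 0 and 2), other list tests in the largest cluster, and left-out replicates for lists and for the interaction.

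The genes named are Rgs14 and Cx3cr1; in each comparison up to 12 higher and 12 lower genes with the largest change among those past the test, with a mean of at least 20 CPM and both Rgs14 KO wells beyond both Control wells; and from each list up to 4 members past the test, or 2 with the smallest p where none passed, given as values. Sex-linked genes and predicted genes are counted but not named. Genes outside this rule are said to be chosen after their values were seen.

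Against TMM, the other scalings moved the median log2 fold change of all genes by between -0.0149 and 0.007 over the 3 comparisons.

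On simulated counts with 200 changed genes, the test in macrophage-like cells (10125 genes) recovered 98% of 4-fold and 73% of 2-fold changes, with 6.60% false calls. In monocyte-like cells (7638 genes) it recovered 99% and 76%, with 6.40% false calls, and in all cells (14012 genes) 80% and 34%, with 9.50% false calls. The interaction test (10039 genes) recovered 79% of 4-fold changes in macrophage-like cells alone. Of 30 simulated lists in macrophage-like cells (10125 genes), camera called all 10 raised lists and 0 of the others. The simulated genes varied independently of each other and without differences in cluster mix between replicates. These rates of false calls, for genes and for lists, need not hold for the real data. CPM below are scaled by TMM unless pooled CPM is written. Folds are those of the edgeR model and need not equal the ratio of the mean CPM. UMIs are counted molecules, so floors of 3 counts cover counting error only. Some items are not reported here.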

Results

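Macrophages and monocytes sorted from the colon lamina propria were profiled by single-cell RNA sequencing to ask what loss of Rgs14, a regulator of G protein signalling, changes in these cells. The libraries of wells 1 to 4 held 109374617, 128871050, 162380236 and 151474252 UMIs. After filtering, 24647 cells remained, 10317 from 3 Rgs14 KO replicates and 14330 from 4 Control replicates. Median depth per replicate lay between 8780 and 12298 UMIs per cell. Median mitochondrial shares were 2.66% and 2.92% in the replicates of well 3, and between 1.66% and 1.76% in the other replicates. The sort left many cells of other types. Macrophage-like cells numbered 3875 and monocyte-like cells 1591; fibroblast and muscle-like, cDC1-like, cDC2-like and plasma cell-like cells made up most of the rest. A cDC is a conventional dendritic cell.

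Macrophage-like cells formed 3 clusters. Cluster 2 (2187 cells) was led by C1q genes, Apoe and Ms4a7, cluster 0 (1116 cells) by Ccr2, Clec4a genes and Trem2, and cluster 4 (572 cells) by Cd163, Folr2 and Pf4. The mix varied between replicates of the same genotype: cluster 0 made up 9.74%, 62.7% and 41.4% of the macrophage-like cells of Rgs14 KO 1-1, 1-2 and 2-2, and 29.9%, 7.44%, 6.34% and 53.7% of those of Control 3-1, 3-2, 4-1 and 4-2. Cluster 2 held most of the class over both genotypes, with 50.3% ± 24.4 (SD, n = 3) in Rgs14 KO and 59.6% ± 21.2 (SD, n = 4) in Control.

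The targeted gene was lower in macrophage-like cells of the Rgs14 KO replicates. Rgs14 (ENSMUSG00000052087; mm10 chromosome 13, 55369732 to 55384687) fell from 13.1 ± 0.845 CPM (SD, n = 4) in Control to 4.56 ± 1.54 CPM (SD, n = 3), a 2.79-fold decrease (log2 fold change -1.48, SE 0.221, edgeR adjusted p = 0.0312). Each of the 3 Rgs14 KO replicates lay below each of the 4 Control replicates, and 34.5% of the Control level was left. The labels do not state which exons were removed, and a 3' assay can still count transcripts of a deleted allele, so the remaining level does not measure the efficiency of deletion. Within the class, pooled Rgs14 fell to 0.721 CPM (5 UMIs) from 12.1 CPM (170 UMIs) in cluster 2 (log2 fold change -4.00, SE 0.516, edgeR adjusted p = 0.00318). In cluster 0 it was 11.1 CPM (49 UMIs) against 15.0 CPM (74 UMIs), a log2 fold change of -0.50 (SE 0.316, adjusted p = 0.511), and in cluster 4, where the low-count filter left it out of the edgeR test, 4.54 CPM (7 UMIs) against 14.2 CPM (44 UMIs). In each of these 3 clusters the Rgs14 KO replicates lay below the Control replicates (exact permutation p = 0.0571, the smallest that 3 against 4 allows). This order rests on few UMIs in some replicates. Cluster 4 held 18 cells of Rgs14 KO 1-2, and cluster 0 held 37 of Rgs14 KO 1-1 and 23 of Control 4-1. In monocyte-like cells Rgs14 stood at 23.2 ± 3.19 CPM against 27.3 ± 6.69 CPM (log2 fold change -0.16, SE 0.217, adjusted p = 0.917). The cDC2-like cells had a log2 fold change of -1.30 (SE 0.256, adjusted p = 0.239), and all cells together -0.26 (SE 0.168, adjusted p = 0.593).

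Transcripts of the recombinase were seen in the Rgs14 KO replicates. Macrophage-like cells held 49 UMIs of Cre there, a pooled 3.80 CPM, and 0 in the 2554 Control cells, which allows up to 0.117% of cells with a UMI; the level was at least 28.0-fold higher, against a floor of 3 counts over the group. The Cre allele and the deletion of Rgs14 therefore go together in this design. Cx3cr1 (ENSMUSG00000052336; chromosome 9, 120048683 to 120068296), the fractalkine receptor whose locus drives the recombinase, fell from 573 ± 121 CPM (SD, n = 4) to 270 ± 20.2 CPM (SD, n = 3) in macrophage-like cells (log2 fold change -1.09, SE 0.173, edgeR adjusted p = 0.0383). In monocyte-like cells Cx3cr1 stood at 32.8 ± 9.13 CPM against 87.0 ± 40.3 CPM (log2 fold change -1.25, adjusted p = 0.121). As only the Rgs14 KO replicates carried the recombinase at this locus, the lower Cx3cr1 cannot be assigned to loss of Rgs14. The edgeR call of Rgs14 was lost without Rgs14 KO 1-2 (adjusted p = 0.0840), Rgs14 KO 2-2 (0.0544), Control 3-1 (0.0763), Control 3-2 (0.0613) or Control 4-1 (0.0848), after thinning (0.254) and with no Scrublet step (0.0887); its adjusted p ranged from 0.000251 to 0.254 over the alternatives. Its log2 fold change stayed negative, between -4.00 in the largest cluster alone and -1.26, and was -3.20 with the class drawn at Leiden resolution 0.5, so the remaining level depends on how the class is drawn.

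**Figure D1:**
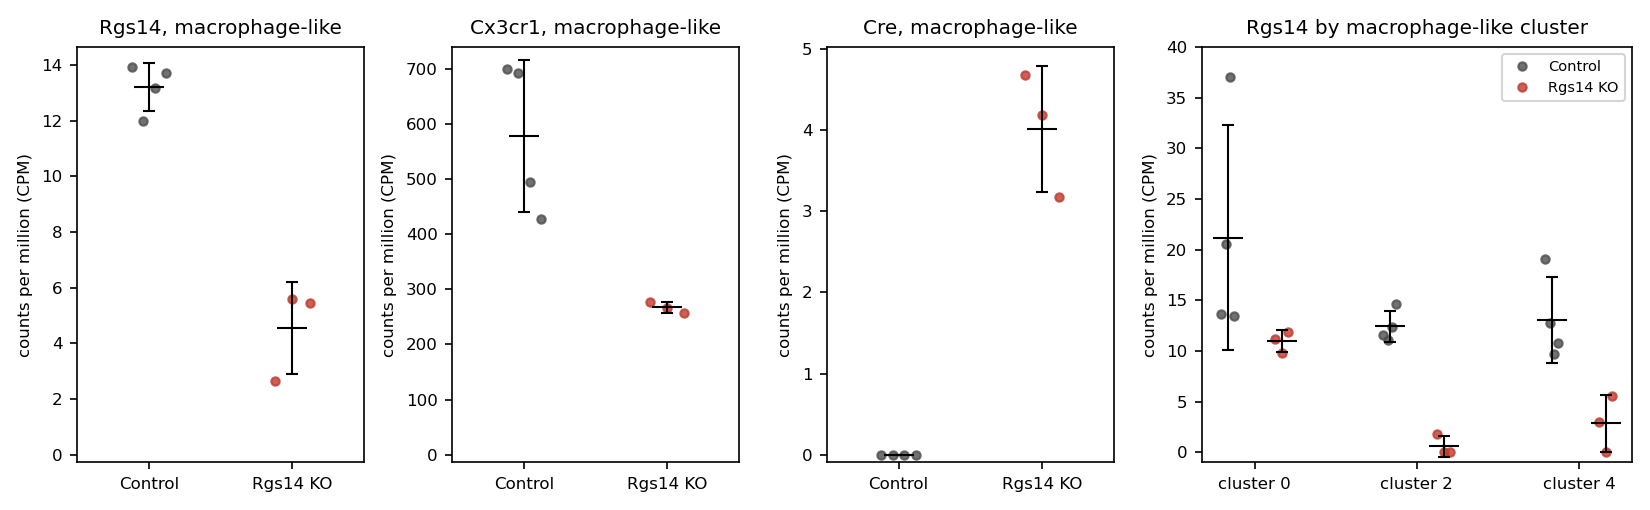
Pooled CPM of Rgs14, Cx3cr1 and Cre in macrophage-like cells of each replicate (points) and of Rgs14 in each macrophage-like cluster, with mean and SD, for Control (n = 4) and Rgs14 KO (n = 3), scaled to the total UMIs of the class. Rgs14 in cluster 2 stands near 0 in the Rgs14 KO replicates (pooled 0.721 CPM), and Cre is at 0 in each Control replicate.

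Macrophage-like cells of the Rgs14 KO replicates had more RNA of interferon-induced genes, Saa3, Cfb, Ccl5, Cdkn1a and Mdm2, and less of Mgl2, Myc and Cenpf. Saa3, an acute-phase serum amyloid A, rose 13.4-fold, from 11.6 ± 9.0 CPM (SD, n = 4) to 149 ± 76.7 CPM (SD, n = 3, log2 fold change 3.75, SE 0.627, edgeR adjusted p = 0.0425). Saa3 stood higher still in unnamed cluster 1, at 1975 ± 1298 CPM in Rgs14 KO and 159 ± 172 CPM in Control. Cfb, given next, was also higher in that cluster, at 121 ± 43.8 CPM in Rgs14 KO and 29.0 ± 11.3 CPM in Control. Il1rn, given below, was among its leading genes. Whether cells or RNA of that cluster entered the macrophage-like values was not tested for these or other genes. Cfb, complement factor B of the alternative pathway, rose 5.80-fold, from 13.8 ± 1.73 to 79.7 ± 15.6 CPM (log2 fold change 2.54, SE 0.167, adjusted p = 9.75e-05). Mgl2, a lectin gene, fell from 319 ± 33.3 to 148 ± 30.7 CPM (log2 fold change -1.10, SE 0.159, adjusted p = 0.0299). Mgl2 was also among the leading genes of the cDC2-like cluster. It stood there at 875 ± 358 CPM in Control and 615 ± 273 CPM in Rgs14 KO (edgeR adjusted p = 0.74).

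The edgeR test called 30 of 10125 genes, 22 higher and 8 lower in Rgs14 KO. Among interferon-induced genes, Irf7, a transcription factor of the type I interferon response, rose 3.47-fold (log2 fold change 1.80, SE 0.203), Ifi205 rose 2.73-fold (1.45, SE 0.124), Ifit3 rose 2.61-fold (1.38, SE 0.218), and Zbp1, a sensor of nucleic acids, rose 2.25-fold (1.17, SE 0.198). Ly6a, the stem cell antigen Sca-1, which interferons induce, rose 3.93-fold (1.97, SE 0.317). Ccl5, a chemokine that attracts T cells, rose 4.56-fold (2.19, SE 0.374), Fpr2, a formyl peptide receptor, 2.43-fold (1.28, SE 0.217), and Il1rn, the antagonist of the interleukin 1 receptor, 2.13-fold (1.09, SE 0.178). Cdkn1a, the cell cycle inhibitor p21, rose 2.44-fold, from 608 ± 213 to 1486 ± 220 CPM (1.29, SE 0.227), and Mdm2, the ubiquitin ligase that restrains p53, rose 2.27-fold (1.19, SE 0.181). Spon1, a matrix protein, rose 3.47-fold (1.80, SE 0.277). Lower with Rgs14, Cx3cr1 and Mgl2 were Cenpf, a centromere protein (-1.99, SE 0.239; 2.25 ± 0.451 against 9.28 ± 1.18 CPM), Myc (-0.91, SE 0.138), Ramp1, a subunit of the receptor for the neuropeptide CGRP (-0.91, SE 0.157), Tmem37 (-0.73, SE 0.108) and Bmyc (-0.63, SE 0.110). The adjusted p of these genes lay between 0.000777 and 0.0477.

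At an unadjusted p under 0.05 there were 1276 genes, against 506 expected by chance. DESeq2 called 125 genes, 98 of them higher, and shared 29 of the 30; sums per well, 2 against 2, called 31, 28 of them higher, with 19 shared. Without Rgs14 KO 1-2 the count was 3, without Rgs14 KO 2-2 or Control 3-1 it was 8, and without Control 3-2 or Control 4-1 it was 5. Of the 20 named genes past the test besides Rgs14, Cfb, Irf7 and Ifi205 kept the call in each of the 7 fits with a replicate left out, and 0 reversed.

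**Figure D2:**
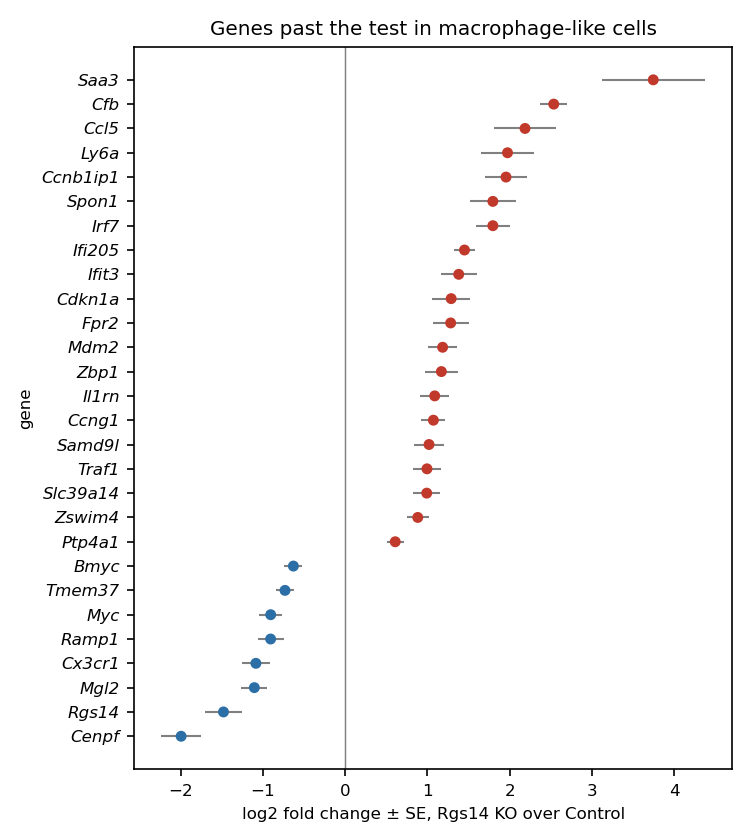
Log2 fold change (Rgs14 KO over Control, n = 3 against 4) of the genes past the edgeR test in macrophage-like cells, points with SE bars, red for higher and blue for lower; Cre, which has no count in Control, and a predicted gene are not drawn. Saa3 has the largest increase (3.75) and Cenpf the largest decrease (-1.99).

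Of 25 gene lists tested in macrophage-like cells, 12 passed camera with its preset correlation, 9 of them higher in Rgs14 KO; with an estimated correlation or with fry 0 passed. Without Rgs14 KO 1-2 or Control 3-2 the count was 7. The type I interferon response list was higher (median log2 fold change 0.83, camera adjusted p = 8.33e-27, adjusted p = 0.288 with an estimated correlation). Each of its 38 tested members had a value above 0, with 3 past the test over all genes and 33 adjusted over the list alone. The interferon gamma list was higher (median 0.45, camera adjusted p = 5.72e-07, adjusted p = 0.288 with an estimated correlation), with 0 of 27 members past the test over all genes and 9 adjusted over the list alone. Its members with the smallest p were Gbp6 (log2 fold change 1.84, adjusted p = 0.0681) and Cxcl9 (2.46, adjusted p = 0.122). Inflammatory cytokines and NF-kB targets were higher (median 0.56, camera adjusted p = 1.29e-09, adjusted p = 0.386 with an estimated correlation), with 30 of 31 members above 0, 2 past the test over all genes (Il1rn and Ccl5) and 8 adjusted over the list alone. Chemokines and their receptors were higher (median 0.37, camera adjusted p = 0.000220, adjusted p = 0.377 with an estimated correlation), with 2 of 26 members (Fpr2 and Ccl5) past the test over all genes and 6 adjusted over the list alone.

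Smaller shifts passed camera in other programmes of the macrophage-like cells. Oxidative phosphorylation genes were higher by a median of 0.14 (camera adjusted p = 0.000778; 36 of 42 above 0; Atp5k 0.42, Uqcrq 0.40). IBD risk genes of myeloid cells had a median of 0.15 (camera adjusted p = 0.00524; Irgm1 0.55, Il12b 2.71). The unfolded protein response (0.19, camera adjusted p = 0.0248; Atf4 0.30, Atf6 0.24), glycolysis and hypoxia (0.22; 0.0311; Ero1l 0.31, Hk2 0.50) and monocyte genes (0.37; 0.0475; Clec4e 1.30, Ly6c2 2.06) were also higher. Lower were RGS and heterotrimeric G protein genes (median -0.09, camera adjusted p = 0.0248; Gna11 -0.84, Rgs10 -0.38), dissociation and heat shock genes (-0.13; 0.0248; Hspa1a -0.81, Klf2 -0.47) and RNA of stromal cells (-0.56; 0.0160; Col3a1 -0.87, Col1a1 -0.93). With an estimated correlation the adjusted p was 0.80 for oxidative phosphorylation, glycolysis, the unfolded protein response and monocyte genes, 0.386 for IBD risk genes, 0.377 for the G protein list, 0.758 for the dissociation list and 0.578 for stromal RNA. In these 8 lists 0 members passed the test over all genes. Adjusted over the list alone, 1 member passed in each of the G protein, dissociation and stromal lists, and 0 in the other 5.

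The other 13 lists did not pass camera in macrophage-like cells. These were Rgs14 neighbours (adjusted p = 0.334; Dok3 -0.34, B4galt7 0.44), Cx3cr1 neighbours (0.687; Csrnp1 0.65, Wdr48 0.30), ERK and immediate early genes (0.695), MHC class II genes (0.145; Cd80 0.49, H2-DMa -0.40), resident and repair macrophage genes (0.146), complement and efferocytosis (0.233; C3 0.65, Ucp2 -0.27), lysosome (0.681; Ctsd 0.25, Ctsl 0.26), cholesterol synthesis (0.166; Insig1 0.32), metallothionein and oxidative stress genes (0.0645; Txnrd1 0.72, Gsr 0.72), cell cycle (0.681), cytosolic ribosomal proteins (0.713; Rpl41 0.35, Rps18 -0.24), plasma cell RNA (0.396; Ighm -0.62, Iglc3 -1.43) and granulocyte RNA (0.259; Mmp8 1.61, S100a9 0.89). Adjusted over the list alone, 4 members were higher in the oxidative stress list and 1 (Cd80) in the MHC class II list, while 3 were lower in the cell cycle list, 2 in plasma cell RNA, and 1 each in the ERK (Myc) and resident macrophage (Mgl2) lists. The median and the camera direction differed in sign for cell cycle (median 0.19), ERK genes (0.02) and Cx3cr1 neighbours (-0.13). The lists of the target with its driver and of lymphocyte RNA had under 5 tested members, and the epithelial, red cell and sex chromosome lists had 0. Pooled haemoglobin stood at 14.9 and 17.0 CPM in macrophage-like cells of Control 4-1 and 4-2 and between 1.68 and 6.65 CPM in the other replicates.

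**Figure D3:**
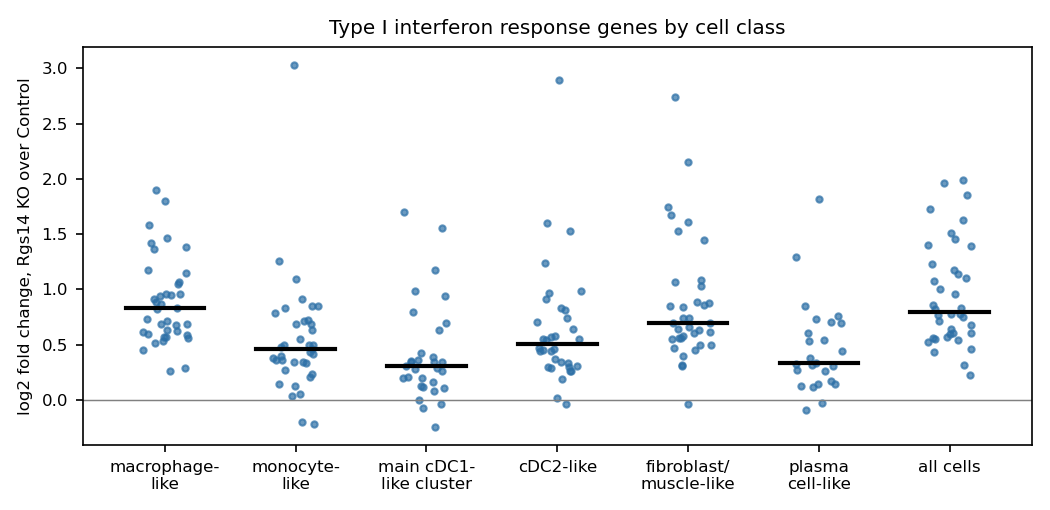
Log2 fold change (Rgs14 KO over Control, n = 3 against 4) of each tested type I interferon response gene (points) by cell class, with the median as a bar. The median is 0.83 in macrophage-like cells, 0.46 in monocyte-like cells and 0.69 in fibroblast and muscle-like cells.

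Monocyte-like cells of the Rgs14 KO replicates had more RNA of interferon-induced genes and of Cfb, and less of Cebpb and Ccl24. Ifi44, an interferon-induced gene, rose from 6.28 ± 3.83 CPM (SD, n = 4) to 29.8 ± 8.42 CPM (SD, n = 3, log2 fold change 3.03, SE 0.415, edgeR adjusted p = 0.0138). Cfb rose from 25.1 ± 8.36 to 53.3 ± 8.05 CPM (1.24, SE 0.225, adjusted p = 0.0497). Ccl24, an eosinophil-attracting chemokine, fell from 25.4 ± 18.6 to 3.46 ± 0.632 CPM (-3.14, SE 0.476, adjusted p = 0.0236). The groups overlapped for Ccl24. Control 3-2 stood at 0, below each Rgs14 KO replicate (2.73 to 3.85 CPM), and the other Control replicates at 23.1 to 40.6 CPM. Cebpb, a transcription factor of myeloid cells, fell from 2249 ± 268 to 1468 ± 10.5 CPM (-0.62, SE 0.115, adjusted p = 0.0497).

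The edgeR test called 10 of 7638 genes in monocyte-like cells, 7 higher and 3 lower. Further increases were Phf11d (2.45-fold, log2 fold change 1.29, SE 0.219) and Slfn4 (2.20-fold, 1.13, SE 0.209), which interferons induce, H2-Q6, an MHC class I gene with close relatives that can share reads (2.32-fold, 1.21, SE 0.196), Odc1, which starts polyamine synthesis (2.04-fold, 1.03, SE 0.184), and Kdm6b, a histone demethylase (1.64-fold, 0.71, SE 0.118). Their adjusted p lay between 0.0332 and 0.0497. At an unadjusted p under 0.05 there were 948 genes, against 382 expected; DESeq2 called 65, with 3 of the 10 shared, and sums per well 3, with 2 shared. Control 4-1 brought most of the Control monocyte-like cells (717), while Control 3-1, 3-2 and 4-2 held 65, 42 and 67. Rgs14 KO 1-1, 1-2 and 2-2 held 345, 162 and 193. Without Control 4-1, which leaves only the sparse Control replicates, 171 genes were called. Without Control 3-1 the count was 0, without Rgs14 KO 1-1, Control 3-2 or Control 4-2 it was 3, and without Rgs14 KO 2-2 it was 2. S100a9, a granulocyte transcript, stood at 158 ± 257 CPM in Control and 16.9 ± 7.30 CPM in Rgs14 KO monocyte-like cells (adjusted p = 0.196).

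In monocyte-like cells 4 of 24 lists passed camera, and 0 with an estimated correlation or with fry. Inflammatory cytokines and NF-kB targets were higher (median 0.45, camera adjusted p = 2.54e-08; 0 of 31 past the test over all genes and 10 adjusted over the list alone; Nlrp3 0.85, Clec4e 0.96). The type I interferon response was higher (median 0.46, camera adjusted p = 4.01e-07; 35 of 37 above 0; 1 past the test over all genes and 14 adjusted over the list alone). The unfolded protein response was higher (median 0.18, camera adjusted p = 0.00467; 0 and 2; Atf4 0.47, Atf6 0.62). Cytosolic ribosomal protein genes were lower (median -0.19, camera adjusted p = 3.16e-07; 44 of 49 below 0; 0 past the test over all genes and 7 adjusted over the list alone; Rpl14 -0.43, Rps18 -0.44). Each of the 4 had an adjusted p = 0.658 with an estimated correlation. MHC class II genes had a median of -0.70 (camera adjusted p = 0.0929; Ciita -1.53, H2-DMb1 -0.86), and the interferon gamma list a median of 0.04 (0.886), against the camera direction and -0.006 with DESeq2.

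The difference of the genotype effect between macrophage-like and monocyte-like cells was tested for 10039 genes, and the edgeR interaction called 0 (smallest adjusted p = 0.203). At an unadjusted p under 0.05 there were 437 genes, against 502 expected, and sums per well called 2. The smallest adjusted p belonged to Irf7, Ly6a and Ccl24 among the genes above: the log2 fold change of Irf7 was greater in macrophage-like cells by 0.99 (SE 0.193) and that of Ly6a by 1.46 (SE 0.299), each at adjusted p = 0.203. For Rgs14 the difference was -1.37 (SE 0.342, adjusted p = 0.459). Without Rgs14 KO 1-1 the count was 3, without Control 3-2 2 and without Rgs14 KO 2-2 1.

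With all cells summed, which mixes expression with cell composition, the edgeR test called 0 of 14012 genes. At an unadjusted p under 0.05 there were 1524 genes, against 701 expected; DESeq2 called 285, limma-voom with the well as a random block 1, and sums per well 0. The smallest adjusted p was that of Rsad2, the interferon-induced viperin, at 50.9 ± 6.40 CPM (SD, n = 3) against 13.02 ± 2.6 CPM (SD, n = 4, log2 fold change 1.97, SE 0.179, adjusted p = 0.0517). Camera passed 13 of 26 lists, 12 of them higher; 0 passed with an estimated correlation and 3 with fry. The type I interferon list was among the 13 (median 0.80, camera adjusted p = 3.10e-28; 33 of 38 adjusted over the list alone), with an adjusted p = 0.269 with an estimated correlation. RNA of granulocytes was higher too (median 1.83, camera adjusted p = 1.35e-06; 8 of 11 adjusted over the list alone, adjusted p = 0.236 with an estimated correlation), with S100a9 at 299.8 ± 36.4 against 58.4 ± 45.4 CPM. Fry also passed the interferon gamma list (camera adjusted p = 1.31e-09, adjusted p = 0.269 with an estimated correlation, fry adjusted p = 0.0473), besides type I interferon and granulocyte RNA (fry adjusted p = 0.0279 each). Camera also passed RNA of lymphocytes (adjusted p = 0.00811, and 0.764 with an estimated correlation) and of plasma cells (0.042, and 0.867).

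Shares of macrophage-like and monocyte-like cells varied between Control replicates by more than they differed between genotypes. Macrophage-like cells were 13.1% ± 1.33 (SD, n = 3) of the cells in Rgs14 KO and 18.1% ± 7.30 (SD, n = 4) in Control, a difference of -5.01 percentage points (exact permutation p = 0.457), which became -7.73 without Control 4-1 and -2.21 without Control 4-2. Monocyte-like cells were 7.53% ± 3.70 against 6.25% ± 8.95, a difference of 1.28 points (exact permutation p = 0.857). In Control 4-1 19.6% of the cells were monocyte-like, against 0.903% to 2.51% in the other Control replicates. Without Control 4-1 the difference rose to 5.74 points, with each Rgs14 KO replicate (3.78% to 11.2%) above each other Control replicate (exact permutation p = 0.1, the smallest that 3 against 3 allows). It was 3.15 without Rgs14 KO 2-2 and 0.0371 without Control 4-2, and it changed sign without Rgs14 KO 1-1 (-0.545), Control 3-1 (-0.157) or Control 3-2 (-0.50). Neutrophil-like cells were 2.05% ± 1.47 against 0.305% ± 0.229, with each Rgs14 KO replicate above each Control replicate (exact permutation p = 0.0571, the smallest that 3 against 4 allows; Benjamini-Hochberg 0.571 over 10 classes). Of the unnamed clusters, cluster 1, with the leading genes Inhba, Il1rn and Il10, made up 13.2% ± 9.14 of Rgs14 KO and 2.44% ± 2.20 of Control cells (exact permutation p = 0.171; Benjamini-Hochberg 0.714 over 25 clusters). Mean shares in Rgs14 KO and Control were 0.112% and 3.5% for cluster 13, 3.31% and 1.19% for cluster 19, 0.022% and 0.042% for cluster 21, 2.24% and 0.708% for cluster 22, and 0 and 0.609% for cluster 24. Cluster 13 had 503 of its 521 cells in Control 4-1. The sort gate sets which cells enter, so these shares describe the sorted sample.

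**Figure D4:**
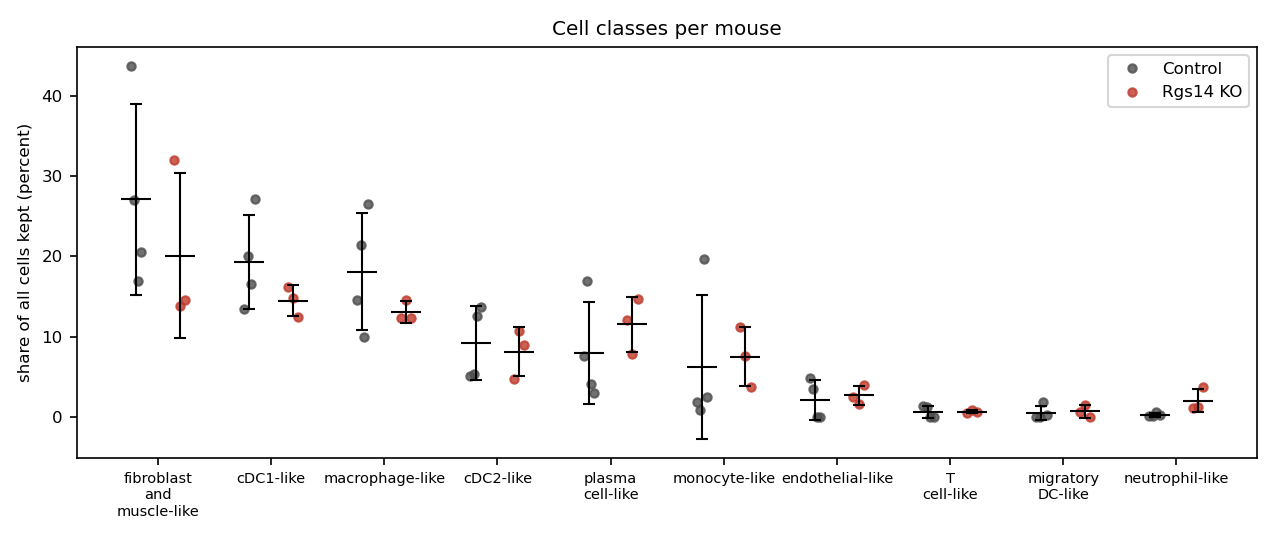
Share of all cells kept (percent) in each named class for each replicate (points), with mean and SD, in Control (n = 4) and Rgs14 KO (n = 3). The monocyte-like share of Control 4-1 stands at 19.6%, apart from the other Control replicates.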

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

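The counts of recombinase transcripts by cell class were chosen after the result was seen.

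In 53 groups of 4 Control replicates (cell class shares, unnamed cluster 1 and the genes past the test), a replicate stood far from the other 3 in 4 groups; chance gives about 2.7. Control 4-1 had 19.6% monocyte-like cells, against 0.903% to 2.51% in the others, and 1.86% migratory DC-like cells, against 0 to 0.225%. Tmem37 stood at 90.0 CPM in macrophage-like cells of Control 4-1, against 101 to 102 CPM, a small gap beside its distance to the Rgs14 KO mean of 59.3 CPM. Rgs14 stood at 37.3 CPM in monocyte-like cells of Control 4-2, against 23.1 to 24.4 CPM.

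Recombinase sequences gave a signal outside the main comparison. ERT2, the tamoxifen-binding part, had 27 UMIs over all cells of the Rgs14 KO replicates, 20 of them in macrophage-like cells, and 0 in Control. Cre had 16 UMIs outside macrophage-like cells in Rgs14 KO and 0 in Control: 7 were in unnamed cluster 1, 3 in cDC1-like cells, 2 each in monocyte-like and cDC2-like cells, and 1 each in neutrophil-like and fibroblast and muscle-like cells.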

How the results depend on the processing

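Hashtags assigned in the plane of both tags, the largest macrophage-like cluster alone, monocyte-like cells with cluster 1, Rgs14 by cluster with no low-count filter, and left-out replicates for lists and for the interaction were chosen after seeing the data. The planned fit without Rgs14 KO replicate 2-1 was not run, as no such cells were found. No paired analysis was possible because the labels give the genotypes no shared replicate numbers. The cause of the changes below was not tested, except that a left-out replicate leaves fewer samples.

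The fold change of Rgs14 in macrophage-like cells kept its direction under all 21 alternatives and its call under 14 of them. It lost the call after thinning (-1.31) and with no Scrublet step (-1.37). The fall was larger at Leiden resolution 0.5 (-3.20), with the hashtag ratio (-2.26), at a mitochondrial limit of 20% (-2.21) and with at least 1000 UMIs and 500 genes in place of the thresholds per well (-1.84), with the call kept in each. It ranged from -1.67 to -1.26 with a replicate left out. With no low-count filter, Rgs14 in clusters 0 and 2 gave -0.49 and -4.00, on the same sides of the threshold (adjusted p = 0.616 and 8.38e-09).

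Genes called in macrophage-like cells numbered 30. DESeq2 gave 125, no low-count filter 93, the well as a random block 52, thinning 51, at least 1000 UMIs and 500 genes in place of the thresholds per well 13, no Scrublet step 10, the hashtag ratio 19, the plane of both hashtags 135, and the largest cluster alone 48; left-out replicates gave 3 to 44. Genes called in monocyte-like cells numbered 10. DESeq2 gave 65, no low-count filter 92, sums per well 3, at least 1000 UMIs and 500 genes in place of those thresholds 4, mitochondrial limits of 5% and 20% 97 and 18, no Scrublet step 23, the hashtag ratio 2, the plane of both hashtags 18, and adding cluster 1 3; left-out replicates gave 0 to 171. In all cells the count of 0 became 285 with DESeq2, 2 with relative log expression scaling, 1 without the low-count filter, 1 with the well as a random block and 2 with the plane of both hashtags; left-out replicates gave 0. The interaction count of 0 became 42 without the low-count filter, 2 with sums per well, 4 at a mitochondrial limit of 5%, 1 with no Scrublet step, 1 with the hashtag ratio, 2 at resolution 0.5 and 4 with the plane of both hashtags; left-out replicates gave 0 to 3.

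Lists past camera in macrophage-like cells (12) became 0 with an estimated correlation and 0 with fry, and 7 to 13 with a replicate left out. In monocyte-like cells (4) they became 0, 0, 7 with the hashtag ratio, 9 with cluster 1 added, and 4 to 6 with a replicate left out.

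The difference in the macrophage-like share, -5.01 points, became -12.4 over macrophage-like and monocyte-like cells only, and ranged from -7.73 to -2.21 with a replicate left out. The difference in the monocyte-like share, 1.28 points, became 12.4 over those cells, reversed to -0.119 per well, and ranged from -0.545 to 5.74 (without Control 4-1) with a replicate left out, reversed at -0.545, -0.157 and -0.50.

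For the single genes named, 3052 values kept their side of the threshold over the alternatives, 232 lost the call and 106 gained it. Another 9, past the test in neither fit, changed sign by more than the SE of the main fit. Smaller changes of sign without a call are counted among the 3052. Among values past the test in either fit, 0 changed sign. Rgs14 is limited by depth: its 4.56 CPM in Rgs14 KO rests on between 9 and 36 UMIs per replicate.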

Other observations

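Several tests were chosen after results were seen. Among them, fibroblast-like cells were taken as cells without the recombinase, an assumption, as 1 Cre UMI was seen in them in Rgs14 KO. The others were those of Rgs14 by macrophage-like cluster, of Slc34a1 and Kxd1 and of the classes in the next paragraph. The list of p53 targets was also chosen then. So were, before their own results were seen, the tests of the interferon list in the largest macrophage-like cluster and with replicates left out. The estimated correlation and fry in that cluster were also added afterwards.

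Interferon-induced genes were also higher in classes outside the sort's targets. In fibroblast and muscle-like cells the edgeR test called 17 of 12042 genes, 15 of them higher in Rgs14 KO (DESeq2 105; sums per well 5). Rsad2 rose from 2.89 ± 1.25 to 20.9 ± 8.18 CPM (log2 fold change 2.74, adjusted p = 0.0123), Ifit1 from 22.0 ± 4.24 to 74.4 ± 18.1 CPM (1.74, adjusted p = 0.00981), Isg15 from 94.5 ± 28.4 to 287 ± 65.9 CPM (1.61, adjusted p = 0.0303) and B2m, the light chain of MHC class I, from 1186 ± 142 to 1991 ± 163 CPM (0.75, adjusted p = 0.0349). The type I interferon list had 35 of 36 members above 0 there (camera adjusted p = 1.24e-28; adjusted p = 0.340 with an estimated correlation; 6 past the test over all genes and 34 adjusted over the list alone). The list was also higher by camera in cDC2-like cells (median 0.51; 4.81e-15; adjusted p = 0.405 with an estimated correlation), plasma cell-like cells (0.33; 1.47e-07; adjusted p = 0.595) and the largest cDC1-like cluster (0.31; 4.46e-07; adjusted p = 0.801). Of 24 lists in each, camera passed 6 in fibroblast and muscle-like cells, 2 in cDC2-like cells, 5 in plasma cell-like cells and 7 in that cDC1-like cluster, and 0 with an estimated correlation; fry passed 1, the G protein list in fibroblast and muscle-like cells (lower, adjusted p = 0.0138). Lists of other cells' RNA and of cell handling were among those past camera: stromal RNA was lower in plasma cell-like cells (median -1.06, camera adjusted p = 0.0151; 5 of 6 lower adjusted over the list alone) and dissociation genes in the cDC1-like cluster (-0.20; 0.00562), as were MHC class II genes in fibroblast and muscle-like cells (-0.53; 1.79e-05). In that cDC1-like cluster 5 of 10283 genes were called. Among them Slc7a5, an amino acid transporter (1.11), and Oas1a (1.70) rose, and Abcg1, a cholesterol exporter (-0.87), and Kxd1 (-0.86) fell, with adjusted p between 0.0239 and 0.0286 (DESeq2 103, sums per well 0). Over all cDC1-like cells 283 of 10632 genes were called, 237 of them higher (DESeq2 460, sums per well 236). That class includes cluster 14, led by Cxcl9, Ifit2 and Rsad2, which made up 1.06% to 2.12% of the cells of each Rgs14 KO replicate and 0.188% to 0.411% of those of each Control replicate (exact permutation p = 0.0571; Benjamini-Hochberg 0.714 over 25 clusters), so the mix of its clusters enters this count. In unnamed cluster 1, 3 genes were called: Mgl2 fell (-2.49, adjusted p = 0.00165), and Irf7 (2.10, adjusted p = 0.00187) and Cfb (2.06, adjusted p = 0.0255) rose, all of which also passed in macrophage-like cells. The edgeR test called 0 genes in cDC2-like cells (758 at an unadjusted p under 0.05, DESeq2 22, sums per well 0) and 0 in plasma cell-like cells (1176, DESeq2 89, sums per well 3).

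A gene beside Rgs14 and a gene on another chromosome stood out after their values were seen. Slc34a1, a phosphate transporter of the kidney (chromosome 13, 55399622 to 55414695), lies next to Rgs14. It had 36 UMIs in Rgs14 KO and 0 in Control macrophage-like cells, at least 20.6-fold higher, and 35 against 0 in monocyte-like cells, at least 13.7-fold higher, against a floor of 3 counts over the group (exact permutation p = 0.0571 each). In cDC1-like cells Slc34a1 had 77 against 20 UMIs (exact permutation p = 0.0571), while in cDC2-like cells, with 112 against 38 UMIs, the groups overlapped (exact permutation p = 0.171), as in fibroblast and muscle-like (3 against 0) and plasma cell-like cells (1 against 0). In all cells Slc34a1 had 293 against 58 UMIs (log2 fold change 2.53, edgeR adjusted p = 0.358). Kxd1 (chromosome 8, 70513396 to 70523180) was lower in each of 6 classes, with no overlap between the groups, which chance gives in 5.71% of splits for a single class. In 7 edgeR fits (5 of those classes, the largest cDC1-like cluster and cluster 1) its log2 fold change lay between -1.01 and -0.41 and its adjusted p between 0.0286 and 0.392, and 1 fit, that of the cDC1-like cluster, passed the test.

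The first pattern weighed is the higher type I interferon list in macrophage-like cells of the Rgs14 KO replicates. Free RNA would bring 0.140% of the difference, and the median with any replicate left out stayed at 0.709 or above, which argue against free RNA and against a single replicate as the cause. Within the largest macrophage-like cluster the median was 0.57, 68.9% of that in the class, with camera adjusted p = 3.29e-18 (0.364 with an estimated correlation, 0.151 with fry), so a different cluster mix cannot be told apart as a part of it. A response only of cells able to carry the recombinase is argued against by the fibroblast median of 0.692. Loss of Rgs14, inflammation of the tissue, and activity of the recombinase acting on other cells through secreted interferon may each account for it. These are hypotheses that were not tested, and the absence of Cre from Control leaves them open. The lower Cx3cr1 of the Rgs14 KO replicates cannot be separated from them in this design either. Each well held mice of 1 genotype. A difference between wells therefore cannot be told apart from genotype, for this list or for any other result here.

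The next pattern is p53 targets: Cdkn1a, Mdm2 and Ccng1 (log2 fold change 1.07, adjusted p = 0.0215, named after its value was seen) rose in macrophage-like cells. With these and Phlda3 (1.65, adjusted p = 0.0712, also chosen after its value was seen) left out, 19 tested members of a list of 30 targets remained. They were higher by camera (unadjusted p = 0.00126, and 0.0172 with an estimated correlation), with a median of 0.204 and 13 of 19 above 0. This argues only weakly against a few genes picked by their call. Camera with its preset correlation also passed 3 to 15 lists in every other split of the replicates. In fibroblast and muscle-like cells the remaining members had a median of 0.005 (quartiles -0.18 and 0.154). In plasma cell-like cells it was -0.03 (quartiles -0.196 and 0.083), and the full list was lower there (camera p = 0.0376, and 0.271 with an estimated correlation). Ccng1 (0.01 and -0.05), Mdm2 (0.20 and 0.10) and Phlda3 (-0.37 and -0.69) moved less in these classes than in macrophage-like cells or the other way. Cdkn1a had 0.81 (edgeR adjusted p = 0.347) and -0.11. The macrophage-like median of 0.204 lay above the upper quartile of both classes, which argues against a rise of that size of the remaining members there. A smaller response of all cells cannot be told apart, as members went both ways and these genes were picked for the pattern. In cDC2-like cells the camera p of the remaining members was 0.00968 (0.0709 with an estimated correlation), with a median of 0.20. It was 0.954 in the largest cDC1-like cluster (median 0.08), and 0.145 in the lower direction in monocyte-like cells (median -0.11). The difference between classes was not tested. Mdm2 (0.91), Ccng1 (0.87), Phlda3 (2.49) and Cdkn1a (0.69) were also higher in cDC2-like cells, with edgeR adjusted p between 0.0707 and 0.48. In the cDC1-like cluster they lay between 0.25 and 0.96. In monocyte-like cells Mdm2 was 0.855 (edgeR adjusted p = 0.0817), Cdkn1a 0.34 and Ccng1 -0.09. Cre is known to cut DNA at sites that resemble its own, so damage by the recombinase may contribute as well as loss of Rgs14; no mice with Cre and wild-type Rgs14 are among the groups, and neither was tested.

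Of the Rgs14 RNA left in macrophage-like cells of Rgs14 KO, the last pattern, free RNA would bring 4.94%, which argues against free RNA as its source. In the Ccr2-led cluster the log2 fold change was -0.50 (-0.491 with no low-count filter) against -4.00 in the largest cluster, and in monocyte-like cells it was -0.16. Fitted together with the replicate as a block, the clusters differed by 3.80 (SE 0.743, edgeR adjusted p = 0.0856). Cells recently derived from monocytes, in which little Rgs14 was lost, may make up the Ccr2-led cluster. Cx3cr1, whose locus drives the recombinase, was also lower in that cluster. Its pooled level in Control was 352 CPM there and 659 CPM in the largest cluster. Pooled Cre in Rgs14 KO was 2.49 CPM (11 UMIs) and 4.61 CPM (32 UMIs). The values therefore cannot tell recent origin from lower expression of the driver. As the cluster mix differs between replicates, the Rgs14 level of the class depends on it too.

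Other splits of the 7 replicates into 3 and 4 bear on whether chance can be excluded. For genes in macrophage-like cells, 3 of the 35 splits gave at least the 30 genes of the real one, and the highest other gave 77, so chance is not excluded. That split sets Rgs14 KO 1-1, Control 3-2 and Control 4-1 apart, the replicates in which cluster 2 holds the greatest part of the macrophage-like cells (75.5% to 80.2%), which points to a structure of the samples. For monocyte-like cells 2 of 35 splits gave at least 10 genes, and chance is not excluded. The highest other gave 117, several times the real count, which also points to a structure of the samples. That split sets Control 3-1, 3-2 and 4-2 apart, the replicates with the fewest monocyte-like cells (42 to 67). For all cells and for the interaction the real count is 0, which 35 of 35 splits must reach, so the splits decide nothing there (highest other 3 and 96); the 96 points to a structure of the samples. For lists, 7 of 35 splits gave at least 12 in macrophage-like cells (highest other 15) and 22 of 35 gave at least 4 in monocyte-like cells (highest other 9), and chance is not excluded for either.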
